A study of Homo sapiens with 5 samples.

How the data were processed

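RNA was sequenced from MD901 cells, a human diffuse large B cell lymphoma line, recovered from tumours that had been grown under the skin of mice given doxycycline in the drinking water. Per the labels, the line carried a retroviral system for doxycycline-induced ectopic expression of HDAC7, and the samples were titled Empty (2 libraries) or HDAC7 (3 libraries). Per the labels' protocols, total RNA was sequenced in paired-end mode with reads of 100 bases, at about 30000000 read pairs per library. The submitters' processing notes name FastQC, STAR 2.7.0a, HTSeq 0.10.0 and DESeq2 with genome build GRCh38, without saying which step each served. The library kit, the strand setting of the read counting and the gene annotation release are not given in the sources used here.

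The deposited table held 60675 genes by Ensembl identifier. Per the file headers, it gave the authors' DESeq2 statistics (base mean, log2 fold change with its standard error, Wald statistic, p-value and adjusted p-value) and 1 column of normalized values for each of the 5 libraries. Each deposited library column was a read count divided by 1 size factor: all values in every column were whole multiples of its smallest value above 0 within a tolerance of 0.01 reads (100% of values), and whole reads were recovered by that division. The mean of the 5 columns equalled the authors' base mean to within 8.73e-11. Size factors ranged from 0.833 to 1.27. The recovered reads summed to 1565595 and 1393311 in Empty replicates 1 and 2, and to 1383938, 1407316 and 1418449 in HDAC7 replicates 1 to 3. A count of 0 allowed up to 3 reads in a library. This floor covers counting error only, since reads without molecular identifiers are not independent molecules.

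Libraries were grouped by their titles. Replicates of a group were compared with a chi-square test of their recovered reads over genes with 20 or more reads. The statistic per degree of freedom was 6.18 to 12.6, so each pair differed by more than sampling noise and all libraries were counted separately. The labels do not state whether each library came from a separate mouse, so p-values measure the spread between these libraries, which may be partly technical.

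The edgeR quasi-likelihood test, planned before the data were examined for unnormalized counts, was not run, because the deposited values were counts divided by size factors. The replacement planned for normalized values was used instead. limma 3.58.1 (R 4.3.3) was fitted with a mean-variance trend to log2(value + 1) on the 5026 genes with a mean value of 10 or more, with group as the only term. Its moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Group levels are given as mean ± SD of the normalized values. Symbols came from a table of Ensembl identifiers that matched 60419 of the genes. Positions, gene types and strands came from GENCODE release 29 (GRCh38), which matched 58444.

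The 27 gene lists (pathways, B cell states and markers of other cell types) were fixed before the data were examined. The 16 lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, two-sided, adjusted over these lists. The same lists were tested with an estimated correlation and with fry. Genes were named by a rule fixed in advance: HDAC7; up to 10 higher and 10 lower genes with a symbol, an adjusted p below 0.05, a mean of 50 or more and groups that do not overlap, ranked by fold change; 5 more each way with a mean of 100 or more, ranked by p; from each list the members with the smallest p; and MYC, BCL6, PRDM1, IRF4, PAX5, TET2, BCL2, CDKN1A and MKI67. Genes named outside this rule are said to have been chosen after their values were seen. A list member that the rule takes is not reported here.

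The fit was tested on simulated counts for the same 5026 genes, drawn with the observed means, the libraries' size factors and a dispersion of 0.022 (the median among the HDAC7 libraries), with 200 changed genes. It recovered 52% of genes changed 2-fold and 99% of those changed 4-fold, with 8 false calls among 159. Of 100 unchanged gene sets, 0 passed 0.05 in camera. Genes were drawn independently of each other, so this does not test how often camera calls unchanged sets whose genes are correlated.

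Alternatives were pseudocounts of 0.1 and 10, no filter on low values, a mean value of 50 or more, scaling on total reads, the replicate number as a block, limma-voom on the recovered reads, an adjusted p threshold of 0.01, a minimum 2-fold change, each library left out in turn, and the authors' deposited statistics. A scaling on protein-coding genes without an exon opposite another gene was added after seeing the data. Overlaps of exons between genes on opposite strands were counted in bases from the annotation. Other analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.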

Results

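Gene expression was measured by bulk RNA sequencing in 5 libraries from MD901 lymphoma cells that had grown as subcutaneous tumours in doxycycline-treated mice. There were 2 libraries titled Empty and 3 titled HDAC7. HDAC7 is a class IIa histone deacetylase, and the design makes 1 comparison, which asks what induced HDAC7 changed in the transcriptome of these tumours. The libraries held between 1383938 and 1565595 reads assigned to genes, and 12692 to 15225 genes had at least 1 read. Of 60675 listed genes, 19870 had a read in some library and 5026 reached the mean value of 10 needed for testing.

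Most assigned reads lay in genes whose exons overlap those of a gene on the opposite strand. Such genes held 92.4% ± 0.987 (SD, n = 5) of the reads. Genes annotated as antisense held 38.1% ± 2.14 (SD, n = 5) and protein-coding genes 36.4% ± 1.03 (SD, n = 5). Protein-coding genes with no exon opposite another gene, 66.2% of all protein-coding genes, held 3.45% ± 0.628 (SD, n = 5). Cytosolic ribosomal protein genes, among the most abundant mRNAs of growing cells, held 0.180% ± 0.0501 (SD, n = 5), and all 37 genes of the mitochondrial chromosome were listed at 0. The antisense gene ENSG00000269968 had a mean of 59776 normalized reads, against 237 for the glycolytic gene GAPDH on the other strand, and RPL30-AS1 had 11286 against 42.4 for RPL30. Among 64 protein-coding list members with an antisense gene overlapping their exons by 200 bases or more, the antisense gene had the higher mean in 54. The counting strand is not given in the sources used here, so reads of a gene and of the gene opposite it cannot be told apart, and levels of overlapping genes are uncertain throughout. Genes named below only because they lie opposite another gene were chosen after their values were seen.

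**Figure D1:**
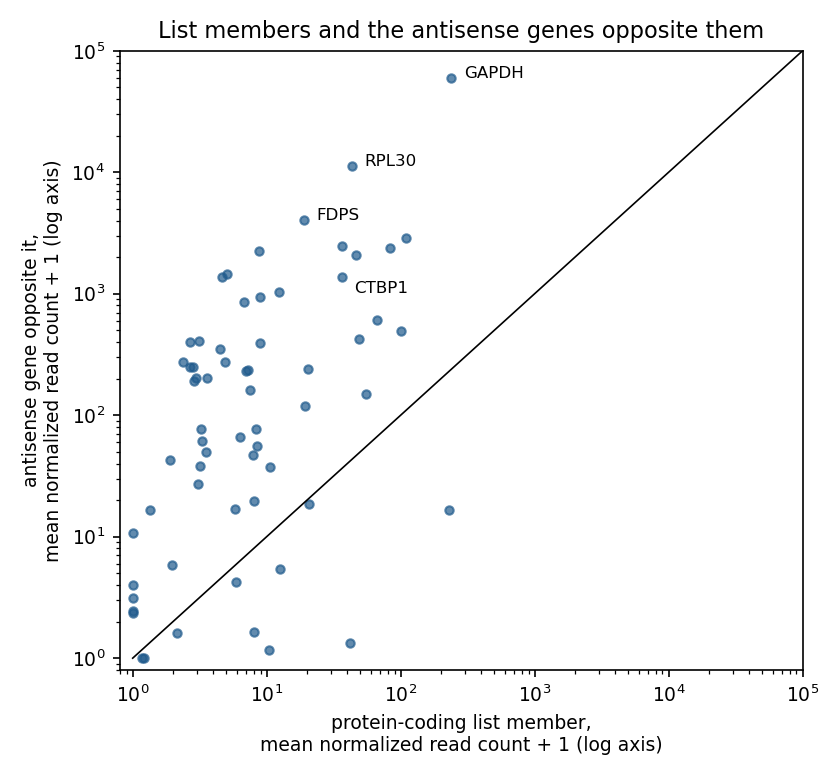
Mean normalized read count plus 1 of protein-coding members of the gene lists (horizontal axis, log scale) and of the antisense gene overlapping their exons (vertical axis, log scale), 1 point per pair, with the line of equal values. The antisense gene had the higher mean in 54 of 64 pairs, including GAPDH, RPL30, FDPS and CTBP1.

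HDAC7 itself was measured first, since it checks the labels. HDAC7 (ENSG00000061273; GRCh38 chromosome 12, 47782722 to 47833132, minus strand) had 14.2 and 9.60 normalized reads in Empty replicates 1 and 2, and 27.2, 27.6 and 20.5 in HDAC7 replicates 1 to 3. Each library titled HDAC7 thus lay above each Empty library, with means of 25.1 ± 4.03 (SD, n = 3) and 11.9 ± 3.27 (SD, n = 2). The log2 fold change was 1.03 ± 0.398 (SE), which did not pass the threshold over all genes (limma adjusted p = 0.301). The antisense gene ENSG00000268069, chosen after its values were seen, overlaps HDAC7 exons by 963 bases. It had 116 and 94.8 normalized reads in the Empty libraries and 293, 166 and 175 in the HDAC7 libraries, a log2 fold change of 0.95 ± 0.277 (SE; limma adjusted p = 0.177).

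HDAC7 and Empty tumours differed in few single genes past the threshold. The largest change was in NECTIN1, which encodes a cell adhesion molecule of the nectin family, with 7.15 ± 0.0647 (SD, n = 2) normalized reads in Empty and 377 ± 130 (SD, n = 3) in HDAC7 libraries. The long noncoding RNA gene KLRK1-AS1 rose from 61.2 ± 34.0 (SD, n = 2) to 302 ± 102 (SD, n = 3). RBM3, which encodes a cold-inducible RNA-binding protein, rose from 21.6 ± 8.52 (SD, n = 2) to 75.1 ± 6.05 (SD, n = 3), while the antisense gene ENSG00000204620 opposite it, at a mean of 1382 against 53.7 for RBM3, had a log2 fold change of -0.13 (limma adjusted p = 0.880). The antisense gene ENSG00000267199, opposite SPIRE1, fell from 489 ± 123 (SD, n = 2) to 178 ± 20.1 (SD, n = 3).

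In all, 6 of 5026 genes passed the threshold, 5 higher and 1 lower in HDAC7 libraries, and 685 had an unadjusted p below 0.05 in limma (302 higher, 383 lower). The unadjusted count compares with 251 expected by chance, and it was 434 without HDAC7 replicate 1. NECTIN1 (ENSG00000110400; chromosome 11, 119623408 to 119729084, minus strand) had a log2 fold change of 5.47 ± 0.309 (SE; limma adjusted p = 9.39e-08). KLRK1-AS1 (ENSG00000245648; chromosome 12, 10363769 to 10398506, plus strand) had 2.34 ± 0.350 (SE; limma adjusted p = 0.0126). RBM3 (ENSG00000102317; chromosome X, 48574449 to 48579066, plus strand) had 1.80 ± 0.318 (SE; limma adjusted p = 0.0381). ATP6V0E2-AS1, ENSG00000230333 and ENSG00000267199 fell outside the naming rule and were chosen after their values were seen. Their log2 fold changes were 3.70 ± 0.371 (SE; limma adjusted p = 0.000133), 2.69 ± 0.437 (SE; limma adjusted p = 0.0230) and -1.44 ± 0.241 (SE; limma adjusted p = 0.0265). ATP6V0E2, on the strand opposite ATP6V0E2-AS1, and AP003393.1, the only gene with exons opposite those of NECTIN1, were listed at 0 in every library, as were KLRK1 and KLRC4-KLRK1 opposite KLRK1-AS1. Since the counting strand is not given, these values of 0 do not settle which strand the reads of NECTIN1, ATP6V0E2-AS1 and KLRK1-AS1 came from. THSD7A, opposite ENSG00000230333, had a mean of 2.23, and SPIRE1, opposite ENSG00000267199, had a log2 fold change of -0.79 (limma adjusted p = 0.356). Scaling on protein-coding genes without an exon opposite, chosen after seeing the data, gave 7 higher and 10 lower genes. The count also depended on single libraries: it was 109 without Empty replicate 1, 39 without Empty replicate 2, 3 without HDAC7 replicate 1, 21 without HDAC7 replicate 2 and 2 without HDAC7 replicate 3. Without HDAC7 replicate 3, KLRK1-AS1, RBM3, ENSG00000230333 and ENSG00000267199 each had a limma adjusted p of 0.344. RBM3 also lost its call without Empty replicate 2 (limma adjusted p = 0.0535) and HDAC7 replicate 1 (0.120), and so did ENSG00000230333 (0.0512) and ENSG00000267199 (0.110) without HDAC7 replicate 1. The log2 fold change of KLRK1-AS1 was 1.75 without Empty replicate 1 and 2.93 without Empty replicate 2.

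**Figure D2:**
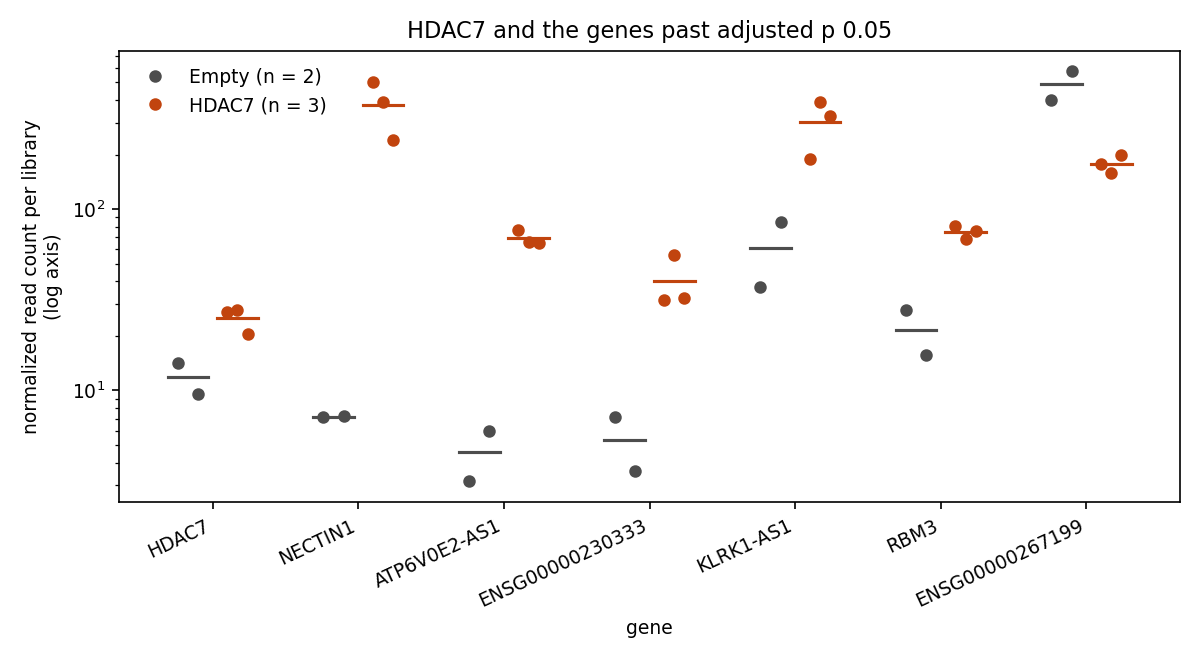
Normalized read count (vertical axis, log scale) of HDAC7 and the 6 genes past the threshold (horizontal axis) in each library, with Empty in grey (n = 2) and HDAC7 in orange (n = 3); horizontal bars are group means. The groups did not overlap in any of these genes, and NECTIN1 went from 7.15 to 377.

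The authors' deposited table called 11 of 19870 genes at an adjusted p below 0.05, 9 higher and 2 lower, of which 5 were also called by limma. Its further calls, chosen after their values were seen, were GAPDH, the antisense gene ENSG00000266954 and 4 mitochondrial pseudogenes on chromosome 1. In the authors' deposited table the log2 fold changes were 1.32 for MTCO1P12, 1.39 for MTATP6P1, 1.13 for MTCO3P12, 1.08 for MTND2P28, 1.17 for GAPDH and -1.47 for ENSG00000266954. The mitochondrial pseudogenes are near copies of mitochondrial genes, all 37 of which were listed at 0, so the origin of the pseudogene reads cannot be told. MTCO1P12 had a mean of 877. Opposite it, ENSG00000230021 had a mean of 106584 and a log2 fold change of -0.20 (limma adjusted p = 0.938). ENSG00000278791, also opposite it, had 95275 and 0.12 (limma adjusted p = 0.968).

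Cytosolic ribosomal protein genes were higher in HDAC7 libraries as a group, by a median log2 fold change of 0.72 over 30 tested members, all with estimates above 0. RPSA, which encodes a small-subunit protein, had 30.2 ± 8.14 (SD, n = 2) normalized reads in Empty and 73.6 ± 10.4 (SD, n = 3) in HDAC7 libraries. RPL19 and RPS3, chosen after their values were seen, had log2 fold changes of 0.79 and 0.91. No member passed over all genes and 17 passed when adjusted over the list alone (limma). The list passed camera at the preset correlation (adjusted p = 1.29e-17), and the adjusted p was 0.216 with an estimated correlation.

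Genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, had a median log2 fold change of 0.75 over 11 tested members, 9 with estimates above 0. ATF4, a stress-induced transcription factor, had 15.3 ± 3.79 (SD, n = 2) normalized reads in Empty and 36.8 ± 9.14 (SD, n = 3) in HDAC7 libraries, and PDIA6, a disulfide isomerase chosen after its values were seen, had 11.3 ± 0.741 (SD, n = 2) and 27.3 ± 5.97 (SD, n = 3). No member passed over all genes, and these 2 passed when adjusted over the list alone (limma). The list passed camera (adjusted p = 0.000268; adjusted p = 0.216 with an estimated correlation).

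MYC target genes, mostly of ribosome biogenesis and metabolism, had a median log2 fold change of 0.43 over 19 tested members, 17 with estimates above 0. LDHA, lactate dehydrogenase A, had 34.9 ± 15.4 (SD, n = 2) normalized reads in Empty and 92.1 ± 14.2 (SD, n = 3) in HDAC7 libraries. The nucleolar protein gene NOP56 and the glycolytic enzyme gene ENO1, both chosen after their values were seen, had log2 fold changes of 1.48 and 1.05, with ENO1 at 0.66 without Empty replicate 2. No member passed over all genes, and these 3 passed when adjusted over the list alone (limma). The list passed camera (adjusted p = 0.000141; adjusted p = 0.284 with an estimated correlation). MYC itself had 10.1 ± 5.81 (SD, n = 2) and 18.0 ± 4.48 (SD, n = 3) normalized reads (limma adjusted p = 0.438), and its log2 fold change of 0.86 was 1.42 without Empty replicate 1 and 0.30 without Empty replicate 2.

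Hypoxia and glycolysis genes had a median log2 fold change of 0.87 over 9 tested members, 6 with estimates above 0. The members with the smallest p were all glycolytic enzymes: GAPDH had 135 ± 23.2 (SD, n = 2) normalized reads in Empty and 305 ± 51.8 (SD, n = 3) in HDAC7 libraries, TPI1, chosen after its values were seen, had 21.2 ± 14.7 (SD, n = 2) and 61.7 ± 13.6 (SD, n = 3), and LDHA also belongs to this list. The log2 fold change of TPI1 was 1.66, and 0.92 without Empty replicate 2. GAPDH had 1.17, and the antisense gene ENSG00000269968 opposite it had 0.15 (limma adjusted p = 0.949). No member passed over all genes, and GAPDH, TPI1 and LDHA passed when adjusted over the list alone (limma). The list passed camera (adjusted p = 0.00258; adjusted p = 0.288 with an estimated correlation).

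Plasma cell genes had a median log2 fold change of 1.02 over 6 tested members, 5 with estimates above 0. JCHAIN, the joining chain of secreted immunoglobulins, had 42.6 ± 17.9 (SD, n = 2) normalized reads in Empty and 87.5 ± 9.91 (SD, n = 3) in HDAC7 libraries, and the surface receptor gene SLAMF7, chosen after its values were seen, had 15.7 ± 0.139 (SD, n = 2) and 41.9 ± 16.3 (SD, n = 3). The log2 fold change of JCHAIN was 1.08, and 0.65 without Empty replicate 2. No member passed over all genes, and these 2 passed when adjusted over the list alone (limma). The list passed camera (adjusted p = 0.00187; adjusted p = 0.284 with an estimated correlation). PRDM1, the master regulator of plasma cells, was listed at 0 in all libraries, and IRF4, at a mean of 9.60, stayed below the filter.

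Proliferation genes had a median log2 fold change of 0.34 over 14 tested members, 13 with estimates above 0. PCNA, the sliding clamp of DNA replication, had 8.92 ± 4.14 (SD, n = 2) normalized reads in Empty and 23.0 ± 3.67 (SD, n = 3) in HDAC7 libraries, and MKI67 had 29.7 ± 28.4 (SD, n = 2) and 29.8 ± 9.73 (SD, n = 3), a log2 fold change of 0.35 that was 1.48 without Empty replicate 1 and -0.78 without Empty replicate 2. No member passed over all genes or when adjusted over the list alone (limma; 1 member with an unadjusted p below 0.05). The list passed camera (adjusted p = 0.0131; adjusted p = 0.284 with an estimated correlation).

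No list kept its call with an estimated correlation, and fry called 0 of 16 lists (lowest adjusted p = 0.0556). Without Empty replicate 2, camera still called ribosomal proteins (adjusted p = 5.06e-11) and the unfolded protein response (adjusted p = 0.0352), while the adjusted p was 0.0934 for MYC targets, 0.0934 for plasma cell, 0.116 for hypoxia and glycolysis and 0.619 for proliferation. Proliferation also lost its call without HDAC7 replicate 2 (adjusted p = 0.0534). In 26 tested members of the called lists with a tested gene opposite them, the members had a median log2 fold change of 0.42, and the opposite genes a median of 0.01. The opposite genes differed between lists: all 7 opposite unfolded protein response members had estimates above 0 (median 0.22, lowest 0.20, highest 0.67), and 7 of 8 opposite ribosomal protein genes had estimates below 0 (median -0.19). In 164 pairs outside these lists whose opposite gene had at least 20 times the value, the median coding value as a percent of the opposite one was 1.97% and 1.31% in Empty replicates 1 and 2, and 2.08%, 2.41% and 1.83% in HDAC7 replicates 1 to 3.

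**Figure D3:**
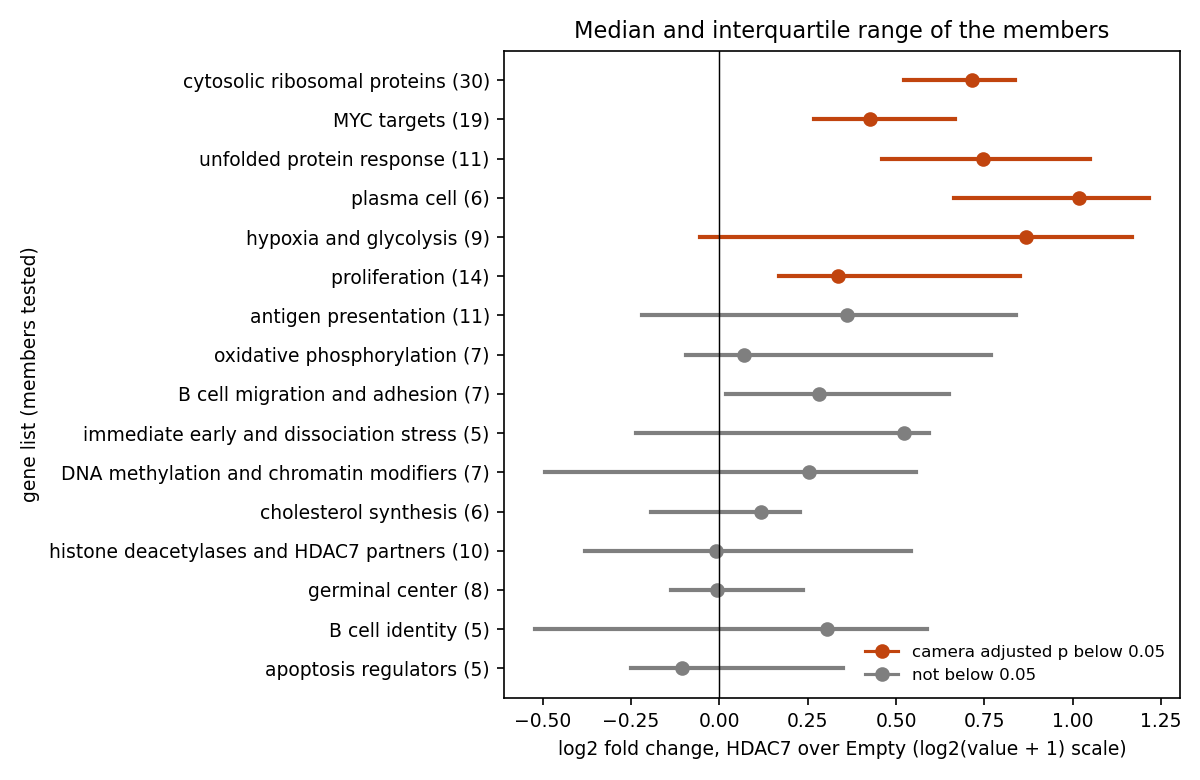
Median (points) and interquartile range (lines) of the log2 fold change, HDAC7 over Empty, on the horizontal axis, for the members of the 16 lists tested (vertical axis, members tested in parentheses), with lists past the camera threshold in orange. The medians of the 6 lists called lay between 0.34 and 1.02.

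The other 10 lists tested did not pass camera (lowest adjusted p = 0.0675, for antigen presentation), although its direction was up for all 16 lists. In this list the class I genes HLA-B and HLA-C had log2 fold changes of 1.72 and 1.62 and the class II gene HLA-DRA 1.08. HLA-B was at 1.11 without Empty replicate 2, and ENSG00000271581, a pseudogene opposite HLA-B with a mean of 1576, had -0.12. HLA-C and HLA-DRA were chosen after their values were seen. These 3 of 11 tested members passed when adjusted over the list alone, and none over all genes (limma). Related HLA genes share near-identical sequence, so their counts are uncertain. In oxidative phosphorylation (camera adjusted p = 0.0782), the ATP synthase genes ATP5F1B and ATP5F1A, the second chosen after its values were seen, had 1.45 and 1.25 and passed over the list alone. In B cell migration and adhesion (camera adjusted p = 0.130), the chemokine receptor gene CXCR4 had 4.56 ± 1.36 (SD, n = 2) normalized reads in Empty and 19.8 ± 3.13 (SD, n = 3) in HDAC7 libraries, and it alone of 7 tested members passed over the list alone.

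B cell identity genes went both ways (camera adjusted p = 0.762). The recombinase gene RAG2 had 180 ± 103 (SD, n = 2) normalized reads in Empty and 65.1 ± 26.3 (SD, n = 3) in HDAC7 libraries, a log2 fold change of -1.42 that moved to -0.80 without Empty replicate 1 and to -2.04 without Empty replicate 2. The surface protein gene CD24, chosen after its values were seen, had a log2 fold change of 1.56, and 1.01 without Empty replicate 2. RAG2 and CD24 passed over the list alone, with no member past over all genes (limma). PAX5, the B lineage commitment factor, had a mean of 5.65, below the filter, and the antisense gene ENSG00000250850 opposite it had 76.5. Germinal center genes (camera adjusted p = 0.749) were split, with 4 of 8 estimates above 0, and none passed over the list alone. BCL6, the transcriptional repressor of this stage, had 5.97 ± 1.74 (SD, n = 2) and 15.3 ± 3.20 (SD, n = 3) normalized reads, a log2 fold change of 1.23 (limma adjusted p = 0.306), and the antisense gene ENSG00000228804, which overlaps its exons and was chosen after its values were seen, had -0.63 (limma adjusted p = 0.301).

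Immediate early and dissociation stress genes (camera adjusted p = 0.373), DNA methylation and chromatin modifiers (0.627), cholesterol synthesis (0.641), histone deacetylases and HDAC7 partners (0.702) and apoptosis regulators (0.762) did not pass in camera, and no member of these lists passed over all genes or when adjusted over the list alone (limma). For histone deacetylases and apoptosis regulators the median (-0.01 and -0.11) and the mean (0.05 and 0.09) differed in sign, as they did for germinal center genes (-0.01 and 0.12). The members of the 5 lists with the smallest p had log2 fold changes of 0.70 for the chaperone gene HSP90AA1, 0.75 for the remodeller gene SMARCA4, 0.69 for FDPS, -0.69 for the corepressor gene CTBP1 and 0.75 for MCL1. HSP90AA1 was at 1.47 without Empty replicate 1 and -0.066 without Empty replicate 2, and MCL1 at 0.26 without HDAC7 replicate 2 and above 0.75 without HDAC7 replicate 3. BCL2, an inhibitor of apoptosis, had 138 ± 17.3 (SD, n = 2) and 128 ± 16.9 (SD, n = 3) normalized reads (limma adjusted p = 0.889). TET2, a DNA demethylase, and CDKN1A, a cell cycle inhibitor, had means of 4.54 and 1.38, below the filter.

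Few markers of other cell types passed the filter on their own strand, where ribosomal protein mRNAs also had few reads, so these values set no limit on other cells. The tumours also grew in mice and the genome build was human (GRCh38), so mouse cells were not measured separately. Whether mouse reads entered the counts was not tested. The highest member of the macrophage list, CD68, had a mean of 8.24 normalized reads, IL7R of the T and NK cell list 6.29 and ALAS2 of the erythrocyte list 3.42, and none of these lists had a tested member. The fibroblast list had 2 tested members, with VIM highest at 45.2 while VIM-AS1 and ENSG00000234961 opposite it had means of 2085 and 3710, the endothelial list 1 (ENG, 41.2) and the keratinocyte, adipocyte and muscle list 1 (KRT10, 11.8). The p53 target list had 3 tested members, of which the death receptor gene FAS had 28.9 ± 8.41 (SD, n = 2) and 8.60 ± 5.59 (SD, n = 3) normalized reads (limma adjusted p = 0.189). The interferon response list had 2 tested members. No member of the NF-kB list (highest TNFAIP3, 8.68) or of the replication-dependent histone list (highest H1-2, 0.769) reached the filter, and the 13 mitochondrially encoded mRNAs were listed at 0. VIM in the fibroblast list and FAS in the p53 list passed when adjusted over the list alone, and no member of any of these lists passed over all genes.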

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

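The scaling on protein-coding genes without an exon opposite, and the set test on the authors' deposited statistics, were chosen after seeing the data. NECTIN1 passed 0.05 in every alternative that gave it a value, and so did ATP6V0E2-AS1, which a mean value of 50 or more left out. KLRK1-AS1 lost its call only without HDAC7 replicate 3. RBM3 passed with pseudocounts of 0.1 and 10 and no filter, but not with scaling on total reads (adjusted p = 0.132), a mean value of 50 or more (0.0617), limma-voom (0.0594) or the authors' deposited table (0.0682), in a range of 0.000133 to 0.678 over 14 alternatives. ENSG00000230333 passed in 8 of 13 alternatives and ENSG00000267199 in 11 of 14. Over the 47 tested genes taken by the naming rule or chosen later, apart from HDAC7, 557 of 633 alternative values kept their sign and their side of the threshold, 54 newly passed it, 17 no longer passed and 5 changed sign. For the 6 called lists, 75 of 93 alternative set tests kept the call and 18 lost it, with adjusted p up to 0.619.

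The 5 higher and 1 lower genes became 48 and 21 with no filter, 2 higher with a mean value of 50 or more, 3 higher with scaling on total reads, 2 and 0 at a threshold of 0.01, 3 lower with a pseudocount of 10, 3 lower with limma-voom, 9 and 2 in the authors' deposited table, and 10 lower with scaling on genes without an exon opposite. That last scaling moved the median log2 fold change of all genes by -0.23; the medians of the 6 called lists stayed above 0, with proliferation at 0.11. The no-filter fit tested 19870 genes and the stricter filter 2350. Other causes were not tested. Lists called numbered 6 in camera, 3 with a mean value of 50 or more, 0 with an estimated correlation and 0 with fry. List members past the threshold numbered 0, against 12 with no filter, 1 with scaling on genes without an exon opposite and 1 in the authors' deposited table. The HDAC7 log2 fold change stayed above 0 in all alternatives that kept it, and a mean value of 50 or more left it out.

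With 1 library left out, higher genes ranged from 2 to 97, lower genes from 0 to 16, list members past the threshold from 0 to 16, lists called from 2 to 8 and the HDAC7 log2 fold change from 0.77 to 1.29. A lone Empty library was assumed to vary like the HDAC7 group. Signs turned in BCL2 (-0.23 to 0.021), HSP90AA1 (-0.066 to 1.47) and MKI67 (-0.78 to 1.48, and -0.022 in the authors' deposited table), none of which was called with all 5 libraries in limma.

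With the replicate number as a block, 3 higher and 0 lower genes passed and 7 lists were called. HDAC7 replicate 3 has no partner, so this fit rests on 4 libraries. Same-numbered libraries correlated at -0.266 and -0.444 in their deviations from the group means. With 2 Empty libraries these deviations mirror each other, so the correlations cannot tell whether same-numbered libraries share a batch. Not run, because the deposited values were not unnormalized counts, were edgeR's quasi-likelihood test, TMM, and edgeR with other size factors. Reads assigned to genes numbered 1383938 to 1565595 per library, against about 30000000 read pairs per library in the labels. The cause of this gap was not tested. Of 19870 genes with a read, 5026 had a mean of 10 or more. PAX5, IRF4, TET2 and CDKN1A lay below it, and whether depth or the counting strand sets their low values was not tested.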

Other observations

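The tests of opposite genes and of explanations in this part were chosen after the results were seen, whereas the HDAC7 fold change and the set tests of the lists were planned. The gene lists were also tested through the genes that lie opposite their members, by 100 bases or more. Of 14 such lists, 0 passed camera (lowest adjusted p = 0.172, for genes opposite cholesterol synthesis, with a median log2 fold change of -0.35), and 0 of their genes passed over all genes. Genes opposite the unfolded protein response had a median of 0.22 and genes opposite ribosomal proteins -0.14.

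Genes with an exon opposite another gene held 91.4% to 93.7% of the reads of each library, and the antisense gene was higher in 84.4% of the 64 pairs with a list member (exact two-sided sign test, p = 2e-08), with genes not being independent replicates. Libraries that do not keep the strand would put the median log2 ratio of antisense gene over list member at or below 0, and it was 3.71 (quartiles 1.62 and 6.09), which argues against them. A candidate explanation is that reads were counted on the strand opposite to the transcript, which needs a strand-keeping kit. The kit is not given in the sources used here, and no biological explanation was tested.

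The 6 lists called by camera at the preset correlation ranked higher in HDAC7 libraries, with 0 called at an estimated correlation and 0 by fry. Camera's direction was up for all 16 lists tested, whereas the median log2 fold change of all 5026 tested genes was -0.07. Coding genes of the 164 pairs outside the called lists, described below, had a median of 0.30. A lean upward was thus not particular to the called lists. If the opposite genes carry most mRNA reads, more mRNA would show in them, but the genes opposite 8 ribosomal protein genes had a median log2 fold change of -0.19 (-0.63 to 0.79), against 0.69 for the ribosomal genes, which lay above their opposite gene in 8 pairs (exact two-sided sign test, p = 0.00781), and this argues against more mRNA of these 8 as a group. For 7 unfolded protein response members the opposite genes all had estimates above 0 (median 0.22, against 0.47 for the members). For 11 members of the other lists the opposite median was 0.0024 with estimates both ways. Among these members GAPDH had 1.17, against 0.15 for ENSG00000269968 opposite it, and members lay above their opposite gene in 7 of the 11 pairs. The own median of the 11 was 0.0068, so as a group these pairs hold no rise to explain and cannot decide. More mRNA stays open for both sets of members and for the ribosomal genes whose opposite gene had the lower mean. It also stays open for members without a tested opposite gene. A larger share of reads on the less common strand in HDAC7 libraries may contribute: in 164 pairs outside these lists, where the opposite gene had at least 20 times the value, the coding gene exceeded it in log2 fold change by a median of 0.46 (116 pairs; exact two-sided sign test, p = 1.12e-07). The groups overlapped in the coding value as a percent of the opposite one, which was lowest in Empty replicate 2 at 1.31%.

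HDAC7 was about 2-fold higher in libraries titled HDAC7, with adjusted p above the threshold. A larger share on the less common strand would leave its opposite gene ENSG00000268069 near other such genes, but its log2 fold change lay at the 97.9th percentile of 1217 genes opposite coding genes, which argues against that share as the only cause. More HDAC7 RNA, read on the opposite strand, may account for both: the change of ENSG00000268069 was 0.95, above the 95th percentile of 0.64. It did not pass over all genes (limma adjusted p = 0.177), and whether the reads came from the introduced or the endogenous gene was not tested.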
